A study of Homo sapiens with 8 samples.

How the data were processed

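The series held 8 arrays of TPC-1 cells, a papillary thyroid carcinoma line. Per the labels' protocols, cells were plated at 100000 per well of a 12-well dish in medium with 10% fetal calf serum and were transfected 24 h later with a cationic lipid reagent, in quadruplicate with each vector. Total RNA was extracted 24 h after transfection, treated with DNase and labelled with Cy3 by the Agilent Low Input kit, per the labels' protocols. The groups were 4 arrays of the empty vector and 4 of the PTCSC3 vector, and replicate numbers came from the sample titles. Nothing in the labels says that the wells came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

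The deposited scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 10.9.1.1 per the file headers. The processed signal in them was background-subtracted and spatially detrended within each array, per the file headers, and not scaled between arrays. A deposited table of log2 values by the submitters covers the same arrays, and per the submitters' processing notes limma was used, with no version or step stated. Its columns correlated best with the scanner signals of their own arrays (r = 0.982 to 0.993), and the slope against log2 scanner signal for bright probes was 0.885 to 1.03, which sets its scale as log2. Its column medians were 5.59, 5.60, 5.66 and 5.60 for empty vector replicates 1 to 4 and 5.60, 5.59, 5.59 and 5.60 for PTCSC3 replicates 1 to 4. The array medians of the log2 scanner signal ran from 4.05 to 5.48, so the deposited values had been brought to a common level between arrays. Given the correlations above, they had not been centred per probe. Their direction follows the scanner signal, and their background treatment and the method of normalization stay unknown. Flags of other kinds (well above background, saturated, outlier, control) came from the deposited files and were used as filters.

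From the scanner files, log2 of the processed signal was taken, spots marked as outliers were left out, spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. Subtracting a percentile leaves differences in the shape of the signal distribution between arrays in place. Of 62976 features 4259 were controls, and the other 58717 made up 42405 probes. A probe was tested if it was well above background on at least 3 of the 4 arrays of a group, which left 26334 probes, with 6 missing values. The files used here pair probes with accessions, and these were matched without versions to a RefSeq table of the human assembly GRCh38.p14, used for names, for the chromosome of the neighbours of PTCSC3 and for the genomic length of genes. This named 25422 probes with 1 symbol each (19483 genes) and left 16983 without a name here. A gene was represented by its tested probe with the highest mean signal, which gave 13766 genes. Where a gene was not well above background on any array of a group, only a bound is given, being the bright group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Such a bound holds for the group means under the main background correction and takes no account of the spread between arrays.

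Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 8 arrays, no block), with Benjamini-Hochberg adjustment over tested probes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 28 lists, and again with an estimated correlation, under which 0 lists were called (lowest adjusted p = 0.783). The test fry, which asks whether a list's genes move one way on balance, gave a lowest adjusted p of 0.212, and its mixed form, which asks for change in either direction, 0.424. The lists, the tests between the vectors, the rule for named genes and most alternatives were fixed before the data were examined. Array weights for the lists, the settings that leave out empty vector replicate 3 together with another normalization, and most tests of technical explanations were chosen after seeing the data. The rule took up to 12 genes per direction past the threshold with non-overlapping groups, those of the largest change. As there were none, it took the 6 genes of smallest p in each direction as values, leaving out predicted and unnamed loci. It also took up to 4 members in the direction of a called list and 2 against it, up to 2 members of each other list, S100A4, VEGFA and MMP9, and the measured neighbours of PTCSC3. Histone genes are given by their current symbols. All 16 genes listed as neighbours lie on the chromosome of PTCSC3 in the RefSeq table. Single values per array were compared with exact permutation tests over 70 relabellings.

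Several points departed from what was planned. The normexp alternative (offset 50) was run on median spot and background signals, which are the raw signals in the files used here. No gene name column was in the files used here, so names came from accessions. All 8 arrays lay on 1 slide, so no slide block was fitted, and the rows of the slide follow the vector.

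The steps were tested on simulated data made from the tested probes' means and variances, with 200 of 26328 probes changed in each of 10 sets. For the comparison of the vectors with all 8 arrays, limma recovered 67.6% of 4-fold, 25.7% of 2-fold and 0.746% of 1.5-fold changes, with a mean of 3.8 false calls. When the same changes were added to the measured arrays the shares were 63.9%, 13.7% and 0.299%, and without empty vector replicate 3 they were 83.2%, 34.0% and 2.69%. For camera, 13765 genes were drawn independently of each other and the ribosomal protein list was shifted by 0.5 log2 units. It was called in 100% of simulated sets. The measured list had an estimated correlation of 0.348 between genes, so this share does not carry over to the measured arrays. The alternatives tried were other background corrections and normalizations, other filters, another variance prior, array weights, the mean of a gene's probes, the replicate number as a block, the deposited values, a threshold of 0.01, and each array left out. No coordinates are given, since the arrays' positions are on another assembly.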

Results

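Gene expression was measured in TPC-1, an established human papillary thyroid carcinoma cell line, after transient transfection with a vector carrying the cDNA of PTCSC3 (papillary thyroid carcinoma susceptibility candidate 3, a long noncoding RNA) or with the empty pcDNA3 vector. Total RNA was taken 24 h after transfection and hybridised to 1-colour Agilent arrays, with 4 arrays for the empty vector and 4 for the PTCSC3 vector. The design asks which transcripts differ in level when PTCSC3 is supplied to these thyroid cancer cells. Each array held 62976 features, and 23404 to 28519 of 42405 probes per array were well above background. After the filter on dim probes, 26334 probes and 13766 named genes were compared. The number of arrays limits the precision of every value below, and each group value is a mean of 4 arrays unless another number is given.

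The supplied transcript itself was not measured here, since no probe carried the RefSeq accession of PTCSC3. The arrays also held 8263 probes for long intergenic noncoding RNAs that are named only by position, and these were not matched to PTCSC3. The level of PTCSC3 therefore does not check the labels.

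Among the arrays, empty vector replicate 3 stood apart from the rest in its gene expression profile. Its mean correlation with the other arrays was 0.916 across tested probes, whereas the mean correlations of the other 7 arrays lay between 0.971 and 0.981. The 75th percentile of its log2 probe signal was 6.71, against 7.90 to 8.88 on the other arrays, while its spike-in controls, RNAs added in known amounts at labelling, had the highest mean of all at 12.1. The first principal component held 73.4% of the variance between arrays and placed this array at 157.9, against -63.7 to 34.1 for the others. Empty vector replicate 4 lay nearest to it, at 34.1. It had the next lowest 75th percentile (7.90) and the highest correlation with replicate 3 (0.953), so leaving out replicate 3 may not remove this difference wholly. Spike-in signals were lower with the PTCSC3 vector, at 11.34 ± 0.17 log2 units (SD, n = 4) against 11.79 ± 0.23 (SD, n = 4), with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allow, and a Benjamini-Hochberg adjusted p of 0.143 over the 5 array measures compared. All 4 empty vector arrays lay in row 1 of the slide and all 4 PTCSC3 vector arrays in row 2, so row and vector cannot be told apart.

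**Figure D1:**
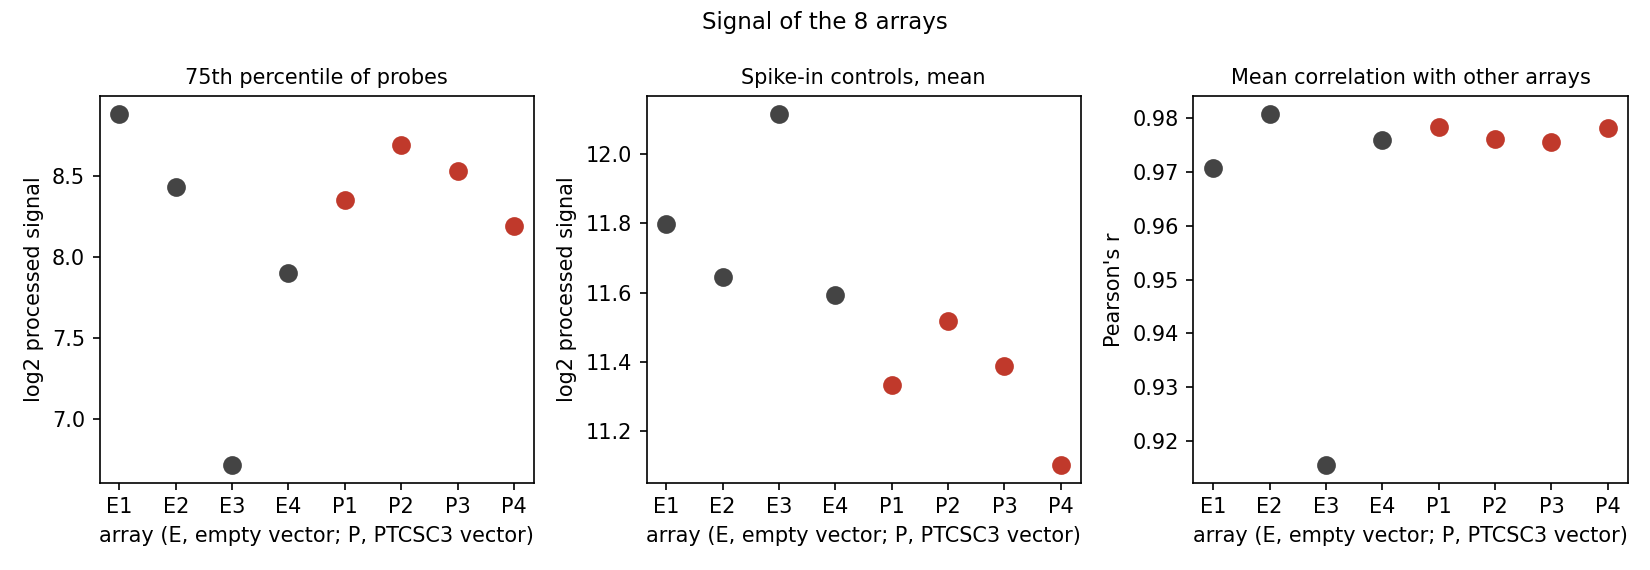
Signal of the 8 arrays, 1 point per array. The panels show the 75th percentile of probe signal and the mean spike-in signal (both log2) and the mean Pearson's r with the other arrays. Empty vector replicate 3 (E3) has the lowest 75th percentile (6.71), the highest spike-in mean (12.1) and the lowest mean r (0.916).

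No gene passed the test between the PTCSC3 vector and the empty vector. With limma, 0 of 13766 genes and 0 of 26334 probes reached an adjusted p under 0.05, and the lowest adjusted p was 0.644. At an unadjusted p under 0.05, 505 genes were found, of which 405 were lower and 100 higher with PTCSC3, against 688.3 that chance gives. Of the genes with higher signal, those with the smallest p were ZC3H7B, an RNA-binding zinc finger protein (log2 difference 1.51, SE 0.33), AIF1L, an actin-bundling protein (0.59, SE 0.14), KLHL15, a ubiquitin ligase adaptor, HHIPL2 (1.22, SE 0.32), LRCH1 (0.66, SE 0.19) and AGBL5, an enzyme that trims glutamates from tubulin (0.78, SE 0.23). KLHL15 was not well above background on any empty vector array and was so on 3 of 4 PTCSC3 arrays. Its bound was at least 1.11-fold higher under the main background correction. With normexp background correction its fitted difference was -0.0059, so a rise of KLHL15 depends on the background handling. Negative control spots were flagged well above background at 0.32% to 2.60% on PTCSC3 arrays and at 0% to 0.65% on empty vector arrays. HHIPL2 was above background on 2 of 4 empty vector arrays, with a value of -5.55 on empty vector replicate 3 far below the other 3. Of the genes with lower signal, those with the smallest p were PRG3, a granule proteoglycan (-0.78, SE 0.16), the pseudogenes PCDHB17P and ADCY10P1, the long noncoding RNA DRAIC, TRMT61A, a tRNA methyltransferase (-0.55, SE 0.13), and CSGALNACT1, an enzyme of chondroitin sulfate synthesis (-1.03, SE 0.26). ADCY10P1 had a difference of -1.09 (SE 0.24). PCDHB17P and DRAIC were not well above background on any PTCSC3 array and were so on 3 of 4 empty vector arrays, which gives bounds of at least 1.90-fold and at least 1.63-fold lower. PRG3 was above background on 3 of 4 empty vector arrays and on 1 of 4 PTCSC3 arrays. All 12 genes had limma adjusted p = 0.644. For each of them the 4 PTCSC3 values lay wholly on 1 side of the 4 empty vector values. This was the case for 836 of 13765 genes, 6.07% against the 2.86% that chance gives, with 632 lower and 204 higher. Further probes of the same gene differed for AIF1L (-0.30 to 0.79), LRCH1 (0.029), TRMT61A (-0.054) and CSGALNACT1 (-0.26).

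The 95% interval of the fold lay within 2-fold for 70.6% of genes and within 4-fold for 97.0%. Each interval holds for 1 gene taken alone and reflects only the spread between these arrays. Since the slide row also follows the vector, the intervals do not exclude a larger effect of PTCSC3. Without empty vector replicate 3 these shares were 93.5% and 99.4%, and limma again called 0 genes, with 552 genes at an unadjusted p under 0.05. That number depended on single arrays, and was 2571 without empty vector replicate 1, 204 without empty vector replicate 4, and 225, 176, 250 and 251 without PTCSC3 replicates 1, 2, 3 and 4. The share of lower genes among those at an unadjusted p under 0.05 was 80.2%, and 67.0% with normexp background correction, 63.5% with normexp and quantile normalization together and 62.2% with the deposited values. It was 61.8% with array weights and 53.3% without empty vector replicate 1, where 1371 genes were lower and 1200 higher.

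S100A4, MMP9 and VEGFA were examined because later work on PTCSC3 in this cell line followed them up. S100A4, a calcium-binding protein tied to cell motility, had a log2 signal of -0.045 ± 0.42 (SD, n = 4) relative to the 75th percentile with the empty vector and -0.64 ± 0.14 (SD, n = 4) with PTCSC3, a difference of -0.60 (SE 0.22). MMP9, a secreted gelatinase, had 1.52 ± 0.24 (SD, n = 4) and 1.03 ± 0.065 (SD, n = 4), a difference of -0.49 (SE 0.15). For both genes all 4 PTCSC3 values lay below the 4 empty vector values, with an exact two-sided permutation p of 0.0286, the smallest that the design allows. Neither passed the test across genes (limma adjusted p = 0.644). Without empty vector replicate 3 the difference was -0.39 for S100A4, whose value on that array lay far above the other 3, and -0.39 for MMP9. Row and vector cannot be told apart for either gene. VEGFA, an angiogenic growth factor, had overlapping values, with a difference of -0.78 (SE 0.41, limma adjusted p = 0.644) for its brighter probe, -0.42 without empty vector replicate 3, and 0.46 (SE 0.37) for its other probe, which was at 0.087 without that array.

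**Figure D2:**
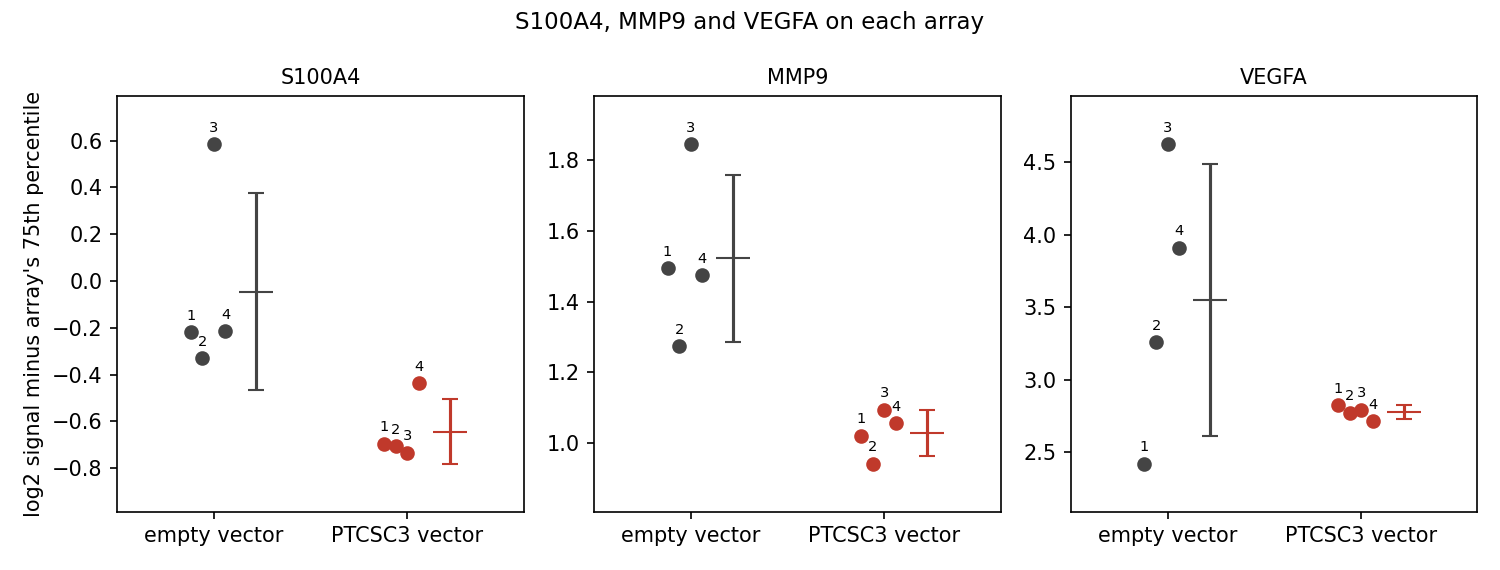
Normalized log2 signal of S100A4, MMP9 and VEGFA (array's 75th percentile set to 0) on each of the 8 arrays. Points are arrays numbered by replicate, bars are means with SD. S100A4 and MMP9 lie lower on all 4 PTCSC3 arrays, by -0.60 and -0.49, and the VEGFA values overlap.

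The calpain and S100 family, in which S100A4 was placed in advance, had 13 measured members, of which 9 were lower with PTCSC3 and 0 passed the test. The median log2 difference was -0.094 (camera adjusted p = 0.125, and adjusted p = 0.783 with an estimated correlation), with no filter on dim probes -0.28 (camera adjusted p = 0.0271), and without empty vector replicate 3 it was -0.15 with 11 members lower (camera adjusted p = 0.0326, and adjusted p = 0.655 with an estimated correlation). On the same 7 arrays the camera adjusted p was 0.0671 with quantile normalization, 0.100 with normexp and quantile normalization together and 0.142 with the deposited values. S100A2, another member, had a difference of -0.56 (SE 0.22, limma adjusted p = 0.644), and its value on empty vector replicate 3 also lay far above the other 3, so that the difference was -0.34 without it. Of the 50 measured genes of cell motility and invasion, 27 were higher, 23 were lower and 0 passed (median 0.081, camera adjusted p = 0.919). In this list SERPINE2, an inhibitor of serine proteases, had a difference of -0.48 (SE 0.14, limma adjusted p = 0.644). Epithelial and mesenchymal markers had a median of -0.20, with 19 of 25 lower (camera adjusted p = 0.0634, 0.0498 with median scaling, 0.0362 with the mean of a gene's probes, 0.287 with no filter, and adjusted p = 0.783 with an estimated correlation). Without empty vector replicate 3 the median was -0.11 with 17 lower (camera adjusted p = 0.255). The list pools epithelial with mesenchymal markers, so its direction does not describe a change toward either state. Among them the keratin KRT8 was at -0.68 (SE 0.28), and at -0.40 without that array, whereas its other probe gave 0.035, while the transcriptional repressor SNAI1 was at 0.40 (SE 0.18).

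Among the 28 gene lists fixed in advance, replication-dependent histones and cytosolic ribosomal proteins were lower with PTCSC3 by camera with a preset correlation. Of 35 measured histone genes, 33 had lower values and 2 higher, with a median log2 difference of -0.36 (camera adjusted p = 0.00579) and 0 members passing on their own. The linker histone H1-3 had -0.82 (SE 0.54), H2AC20 -0.83 (SE 0.52), H2BC21 -0.91 (SE 0.65) and H2AC17 -0.65 (SE 0.48), while H3C1 had 0.049 (SE 0.14) and H2BC14 0.0070 (SE 0.26), the latter turning to -0.0026 with quantile normalization. Of 56 measured ribosomal protein genes, 43 had lower and 13 higher values, with a median of -0.15 (camera adjusted p = 0.00266) and 0 members passing. Here RPS28 had -0.45 (SE 0.22), RPL34 -0.47 (SE 0.24), RPL8 -0.36 (SE 0.18) and RPL36 -0.30 (SE 0.15), against 0.36 (SE 0.21) for RPL15 and 0.18 (SE 0.15) for RPL4. Neither list was called with an estimated correlation (adjusted p = 0.914 for each). Empty vector replicate 3, the array that stood apart, exceeded the mean of the PTCSC3 arrays by a median of 1.63 log2 units over the histones and 0.31 over the ribosomal proteins. Without it the histone median was 0.047 (camera adjusted p = 0.891), with 22 of 35 genes higher, and the ribosomal median was -0.051 (camera adjusted p = 0.151), with 44 of 56 genes lower. The differences without it were -0.25 for H1-3, -0.31 for H2AC20, -0.21 for H2BC21, -0.18 for H2AC17, 0.19 for H2BC14, -0.24 for RPS28, -0.25 for RPL34, -0.22 for RPL8, -0.19 for RPL36, 0.17 for RPL15 and 0.073 for RPL4. With array weights the histone median was -0.13 (camera adjusted p = 0.131) and the ribosomal median -0.090 (camera adjusted p = 0.00256). Without PTCSC3 replicate 3 the medians were -0.30 and -0.098 (camera adjusted p = 0.0772 for each), without empty vector replicate 4 the histone median was -0.31 (camera adjusted p = 0.0532), and without empty vector replicate 1 it was -0.75. With normexp the histone median was -0.22 (camera adjusted p = 0.0575) and the ribosomal median -0.016 (camera adjusted p = 0.452). The ribosomal median turned to 0.053 with quantile normalization, to 0.075 with normexp and quantile normalization together and to 0.12 with the deposited values.

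**Figure D3:**
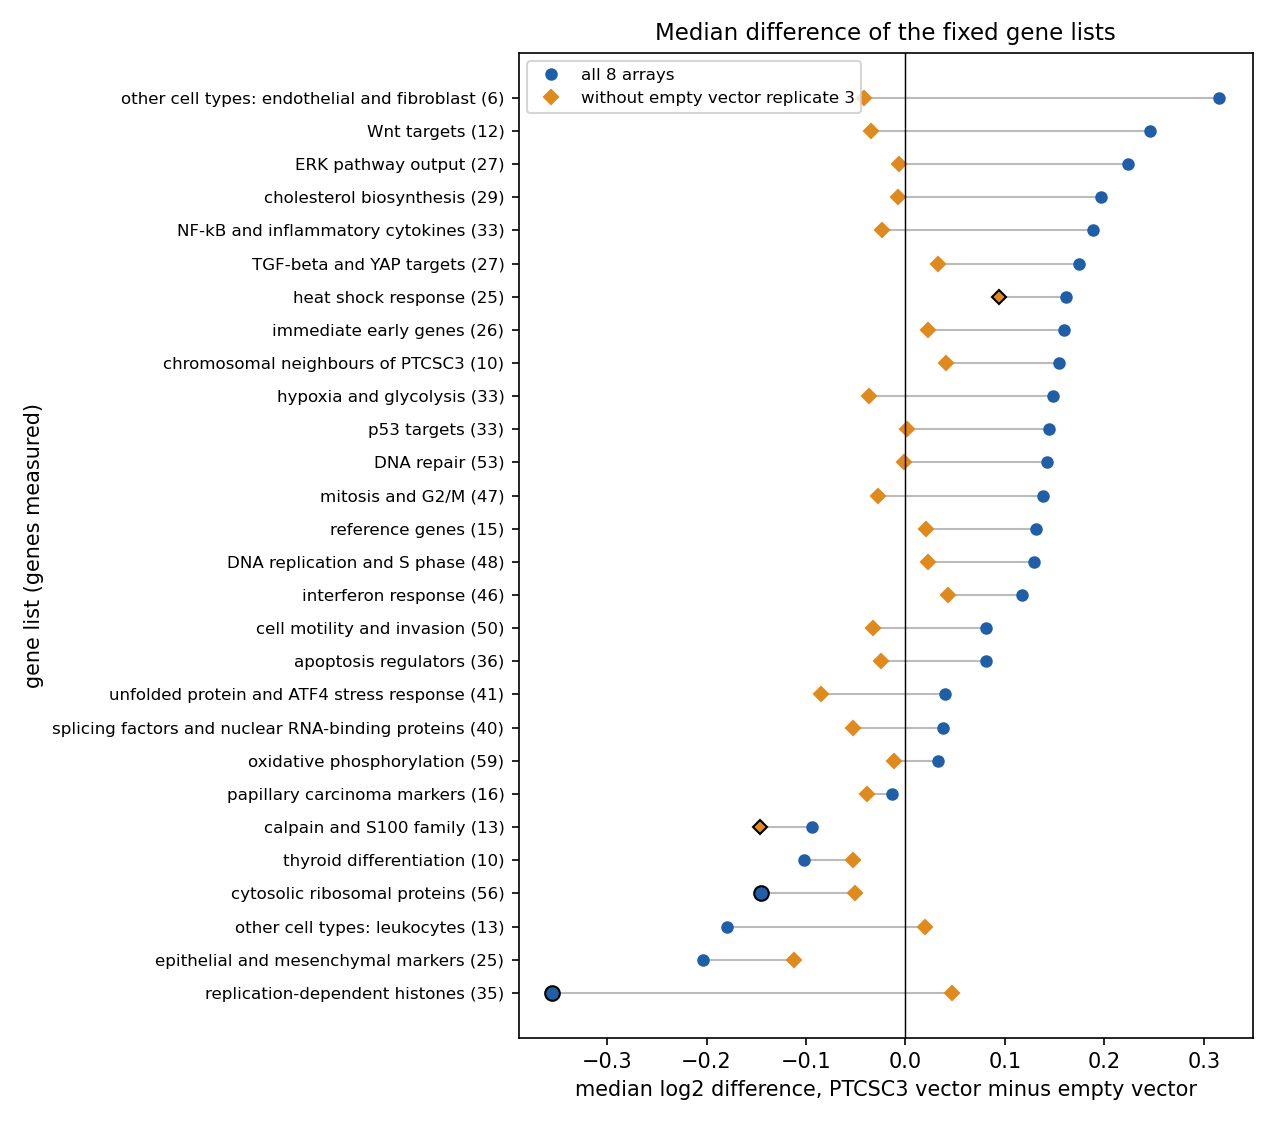
Median log2 difference (PTCSC3 vector minus empty vector) of the 28 gene lists fixed in advance, with the number of genes measured in brackets. Circles are all 8 arrays, diamonds are the 7 arrays without empty vector replicate 3, and black outlines mark a camera adjusted p under 0.05 with the preset correlation. The histone median moves from -0.36 to 0.047 when that array is left out, and the ribosomal median of -0.15 turns to 0.053 with quantile normalization.

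The remaining lists did not pass the test with all 8 arrays. Over all 13766 genes the median log2 difference was 0.045, and -0.013 without empty vector replicate 3. List medians and counts of higher members, here and above, are to be read against these values. Of the members of all 28 lists 0 passed, over all genes tested or adjusted over the list alone. The list medians kept their direction under each scaling of all 8 arrays except where stated, but 15 of the 28 changed sign without empty vector replicate 3, and 10 did so with array weights. Of 48 genes of DNA replication and S phase 34 were higher (median 0.13, camera adjusted p = 0.232, 0.0271 with no filter, with normexp 0.20 and camera adjusted p = 0.0183, and adjusted p = 0.914 with an estimated correlation), of 47 genes of mitosis and G2/M 33 were higher (0.14, camera adjusted p = 0.358), and of 53 DNA repair genes 33 were higher (0.14, camera adjusted p = 0.582). The members with the smallest p nevertheless had lower values, such as DTL at -0.47 (SE 0.18), FANCI at -0.67 (SE 0.24) and PRKDC, the DNA-dependent protein kinase, at -0.47 (SE 0.17). The p53 targets had 25 of 33 higher (0.14, camera adjusted p = 0.232, 0.0320 with no filter, and adjusted p = 0.914 with an estimated correlation), or 17 of 33 without empty vector replicate 3 (0.0011, camera adjusted p = 0.495). Among them the cell cycle inhibitor CDKN1A was at 0.31 (SE 0.14), with overlapping values. GADD45A went the other way, at -0.32 (SE 0.15), with all PTCSC3 values below the empty vector values. The apoptosis regulators had 21 of 36 higher (0.081, camera adjusted p = 0.815), with the BCL2 family member BAD at -0.42 (SE 0.15). This list pools genes that promote and genes that oppose apoptosis, so its median gives no direction for that process.

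Of 46 interferon response genes 31 were higher (0.12, camera adjusted p = 0.482), although the RNA sensor IFIH1 was at -0.34 (SE 0.12) and PARP14 at -0.34 (SE 0.13). NF-kB and inflammatory cytokine genes had 23 of 33 higher (0.19, camera adjusted p = 0.363), with TNFAIP3, an inhibitor of NF-kB signalling, at -0.35 (SE 0.14). Heat shock genes had 18 of 25 higher (0.16, camera adjusted p = 0.238), with the mitochondrial chaperonin HSPE1 at 0.41 (SE 0.23) but DNAJB4 at -0.71 (SE 0.33). Without empty vector replicate 3, 20 of 25 heat shock genes were higher (0.094, camera adjusted p = 0.0326, and adjusted p = 0.987 with an estimated correlation). On those 7 arrays the camera adjusted p of this list was 0.0398 with quantile normalization, 0.138 with normexp and quantile normalization together and 0.112 with the deposited values. The unfolded protein and ATF4 response had 22 of 41 higher (0.039, camera adjusted p = 0.659). Immediate early genes had 17 of 26 higher (0.16, camera adjusted p = 0.582), with the nuclear receptor NR4A2 at -1.23 (SE 0.49). Genes of ERK pathway output had 23 of 27 higher (0.22, camera adjusted p = 0.125, 0.0148 with no filter and 0.0311 without empty vector replicate 1, and adjusted p = 0.914 with an estimated correlation). The receptor EPHA2 was at 0.58 (SE 0.26), whereas EPHA4 was at -0.35 (SE 0.16). Without empty vector replicate 3 the differences were 0.34 for EPHA2, -0.24 for EPHA4, -0.31 for DTL and -0.44 for FANCI. On the same arrays they were 0.21 for HSPE1, -0.45 for DNAJB4 and -0.80 for NR4A2.

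TGF-beta and YAP targets had 18 of 27 higher (0.17, camera adjusted p = 0.663), with the vasoactive peptide gene EDN1 at -0.59 (SE 0.16), and Wnt targets 8 of 12 higher (0.25, camera adjusted p = 0.582). Hypoxia and glycolysis genes had 24 of 33 higher (0.15, camera adjusted p = 0.238), with the collagen prolyl hydroxylase P4HA1 at -0.48 (SE 0.18). Cholesterol biosynthesis genes had 22 of 29 higher (0.20, camera adjusted p = 0.238). Oxidative phosphorylation had 33 of 59 higher (0.032, camera adjusted p = 0.989) and splicing factors 22 of 40 higher (0.038, camera adjusted p = 0.901), with SF3A1 at 0.73 (SE 0.26), and at 0.47 without empty vector replicate 3. SRSF11, also a splicing factor, went the other way, at -1.06 (SE 0.44), and at -0.62 without that array. Further probes of SRSF11 gave -0.96 to 0.0020. For apoptosis, the unfolded protein response, motility, oxidative phosphorylation and splicing the median and mean were above 0 whereas camera gave the direction as down. This test compares the mean test statistic of a list with that of all other genes. The medians of the unfolded protein response, oxidative phosphorylation and splicing lay below the 0.045 of all genes. Those of apoptosis and motility, each 0.081, lay above it. Single arrays lay far from their group for DTL and P4HA1 (empty vector replicate 3), IFIH1 (empty vector replicate 2), NR4A2 (PTCSC3 replicate 3) and BAD (PTCSC3 replicate 4). Over the lists of higher median, empty vector replicate 3 lay below the mean of the PTCSC3 arrays, by a median of -0.49 for DNA replication, -0.51 for interferon response and -0.90 for ERK pathway output. Without that array their medians were 0.022, 0.042 and -0.0067, and those of immediate early genes and TGF-beta and YAP targets were 0.022 and 0.033.

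Thyroid differentiation genes had 10 measured members, 5 higher and 5 lower (median -0.10, and 0.016 with quantile normalization, camera adjusted p = 0.732), including PAX8, a thyroid transcription factor, at -0.29 (SE 0.15) and thyroglobulin, TG, at -0.30 (SE 0.15). Papillary carcinoma markers had 8 of 16 higher (-0.013, and 0.039 with normexp, 0.014 with quantile normalization and 0.0021 with median scaling, camera adjusted p = 0.815), with KRT19 at -0.41 (SE 0.19). Markers of leukocytes had 3 of 13 higher (-0.18, camera adjusted p = 0.238), markers of endothelium and fibroblasts 5 of 6 higher (0.32, and -0.086 with normexp, camera adjusted p = 0.363), and reference genes 8 of 15 higher (0.13, camera adjusted p = 0.638). Over the leukocyte markers empty vector replicate 3 exceeded the PTCSC3 arrays by a median of 0.56, and over the endothelial and fibroblast markers it lay below them by a median of -1.63. Without that array the medians were -0.052 for thyroid differentiation, -0.038 for papillary carcinoma markers, 0.019 for leukocytes, -0.042 for endothelium and fibroblasts and 0.021 for reference genes, and the differences were -0.19 for TG and -0.24 for KRT19. Of the chromosomal neighbours of PTCSC3, 10 were measured, 8 of them higher (0.15, camera adjusted p = 0.50). The values were 0.57 (SE 0.27) for RALGAPA1, 0.78 (SE 0.55) for BRMS1L, 0.33 (SE 0.29) for NFKBIA, 0.20 (SE 0.21) for PPP2R3C, 0.17 (SE 0.37) for MBIP, 0.14 (SE 0.27) for FOXA1, 0.11 (SE 0.17) for SLC25A21, 0.046 (SE 0.14) for PSMA6, -0.43 (SE 0.61) for PAX9 and -0.52 (SE 0.26) for MIPOL1, with limma adjusted p of 0.644 or more. Without empty vector replicate 3, the list median was 0.041, MBIP turned to -0.19, FOXA1 to -0.074 and PAX9 to 0.23, and the differences of the others were 0.30 for RALGAPA1, 0.26 for BRMS1L, 0.047 for NFKBIA, 0.035 for PPP2R3C, 0.011 for PSMA6, 0.14 for SLC25A21 and -0.30 for MIPOL1. With normexp SLC25A21 turned to -0.098, MBIP to -0.018 and FOXA1 to -0.13. Further probes gave -0.22 for RALGAPA1 and -0.24 for MBIP.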

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

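The tests of signal against spike-ins, of leaving out empty vector replicate 3 and of the slide row were chosen after the results were seen, while the tests of gene length and of other splits were set beforehand. Values are log2 signals relative to each array's 75th percentile unless another unit is named. A single array lay far from the other 3 of its group in 15 of 236 sets of 4 values examined, where chance gives 11.8, and 8 of the 15 were empty vector replicate 3.

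Empty vector replicate 3 was far from its group in mean correlation with the other arrays, at 0.916 against 0.971 to 0.981. A weaker hybridization or scan of the whole array is argued against by its spike-in mean, which lay 0.32 log2 units above the highest of the other arrays. Less labelled cell RNA on this array remains open and is consistent with its 75th percentile relative to the spike-ins, which lay -1.71 log2 units from the lowest of the other arrays. A loss of longer transcripts, as in degraded RNA, may add to this, since Spearman's rho across 13766 genes between genomic length and the array's deviation was -0.15, against -0.11 to 0.24 for the other arrays. Genomic length stands in poorly for transcript length, genes are not independent replicates, empty vector replicate 4 came close at -0.11, and no biological explanation was tested, because the labels give this array no treatment of its own.

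The lower histone and ribosomal protein lists were weighed against this array as the sole source. The histone median was -0.36 with all arrays and 0.047 without it, with 33 and 13 of 35 genes lower, which is consistent with that explanation. For the ribosomal proteins it stays undecided, since the median was -0.15 and -0.051, but 43 of 56 genes were lower with that array and 44 without it. The lower ribosomal median also depended on the processing. With all 8 arrays it was -0.016 with normexp, 0.053 with quantile normalization, 0.075 with both together and 0.12 with the deposited values. A smaller effect of PTCSC3 stays open, as untested. Of 35 splits of the 8 arrays into 4 and 4, 28 gave at least as many called lists as the real 2, and the highest of the other splits gave 9, so chance cannot be excluded for the number of lists.

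S100A4 and MMP9, lower on each PTCSC3 array, were weighed in the same way. Empty vector replicate 3 as the sole source is argued against, since without it the differences were -0.39 (SE 0.12) for S100A4 and -0.39 (SE 0.11) for MMP9, each over 3 times its SE below 0. Both genes had non-overlapping groups with all arrays, so leaving out 1 array could not change their direction. Only the size of the difference was put to the test. The row of the slide stays open for both genes and cannot be told apart from the vector, because each row held 1 group, and the spike-in controls differed between the rows by -0.45. An effect of PTCSC3 stays open too, as no array of either vector lay in the other row. Chance stays open across genes, as 836 genes had non-overlapping groups and neither gene passed after adjustment.

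The other values far from their group were as follows. In empty vector replicate 3, S100A4 was 0.58 (others -0.33 to -0.22), S100A2 was 7.78 (others 6.84 to 6.97), HHIPL2 was -5.55 (others -4.33 to -4.14), DTL was 2.86 (others 2.17 to 2.25), BIRC5, an inhibitor of apoptosis with a role in mitosis, was 6.72 (others 6.24 to 6.28), P4HA1 was 2.49 (others 1.94 to 1.99) and the complex I subunit NDUFS5 was 6.84 (others 6.31 to 6.35). In empty vector replicate 2, AIF1L was -1.86 (others -1.58 to -1.53) and IFIH1 was 3.44 (others 3.63 to 3.66). In PTCSC3 replicate 3, H2BC14 was 1.53 (others 1.71 to 1.71) and NR4A2 was -4.76 (others -3.64 to -3.44). In PTCSC3 replicate 4, S100A4 was -0.44 (others -0.73 to -0.70), BAD was 3.18 (others 3.04 to 3.06) and the smooth muscle actin ACTA2 was 0.69 (others 0.63 to 0.63).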

How the results depend on the processing

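The settings that leave out empty vector replicate 3 together with another normalization, and array weights for the lists, were chosen after seeing the data, and the others were planned. The count of genes changed was 0 by limma in every setting, with the lowest adjusted p between 0.12 (array weights) and 0.974 (without empty vector replicate 3). With the replicate number as a block, limma also called 0 genes, 373 were at an unadjusted p under 0.05, and 2 lists were called. Same-numbered arrays correlated at -0.17, 0.36, -0.18 and 0.13 in their deviations from the group means, and 2 of 4 correlated best with their own number. Whether the numbers pair the arrays stays undecided. Empty vector replicate 3 weighs on its group mean, and the replicate number is also the column of the slide. The count of genes at an unadjusted p under 0.05 was 505, and it was 1557 with array weights, 863 with the deposited values, 996 with normexp and quantile normalization together, 176 to 2571 with 1 array left out, and, with empty vector replicate 3 left out, 904 with the deposited values and 1096 with normexp and quantile normalization. The number of lists called was 2, and it was 1 each with normexp, quantile normalization, both together and the deposited values (DNA replication with normexp, histones in the other 3), 6 with no filter, 1 with array weights (ribosomal proteins), 0 with an estimated correlation, 0 to 3 with 1 array left out, and, with empty vector replicate 3 left out, 1 with quantile normalization, 0 with normexp and quantile normalization and 0 with the deposited values. The histone median of -0.36 became -0.22 with normexp (adjusted p = 0.0575), -0.13 with array weights (adjusted p = 0.131), kept its value of -0.36 with an estimated correlation (adjusted p = 0.914), ranged from -0.75 to 0.047 with 1 array left out, and with empty vector replicate 3 left out was 0.060 with quantile normalization, 0.074 with normexp and quantile normalization and 0.088 with the deposited values. The ribosomal median of -0.15 became -0.016 with normexp, 0.053 with quantile normalization, 0.075 with normexp and quantile normalization, 0.12 with the deposited values and -0.15 with an estimated correlation (adjusted p = 0.914), ranged from -0.18 to -0.051 with 1 array left out, and with empty vector replicate 3 left out was -0.011 with quantile normalization, -0.014 with normexp and quantile normalization and -0.0052 with the deposited values. The cause of these changes was not tested, apart from leaving out the array that stood apart, without which the histone median reversed.

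Of the 28 list medians, 15 changed sign without empty vector replicate 3, and most of the other reversals share that array. With 1 array left out, the medians that changed sign ranged as follows, besides the histones, with NF-kB -0.024 to 0.34, mitosis -0.027 to 0.28, DNA repair -0.0010 to 0.26, apoptosis -0.024 to 0.16, the unfolded protein response -0.085 to 0.11, ERK output -0.0067 to 0.45, motility -0.033 to 0.15, Wnt -0.034 to 0.45, hypoxia -0.036 to 0.23, cholesterol -0.0072 to 0.23, oxidative phosphorylation -0.012 to 0.082, splicing -0.052 to 0.15, thyroid differentiation -0.13 to 0.0061, papillary markers -0.044 to 0.028, leukocytes -0.28 to 0.019 and endothelium and fibroblasts -0.042 to 0.57. With quantile normalization and empty vector replicate 3 left out, the reversed medians were NF-kB -0.020, mitosis -0.013, apoptosis -0.00085, the unfolded protein response -0.046, motility -0.0070, Wnt -0.037, cholesterol -0.0037, splicing -0.026, leukocytes 0.012 and endothelium and fibroblasts -0.047. With normexp and quantile normalization and that array left out, the reversed medians were NF-kB -0.0057, mitosis -0.020, DNA repair -0.0017, p53 -0.021, apoptosis -0.0097, the unfolded protein response -0.041, Wnt -0.020, oxidative phosphorylation -0.0045, splicing -0.017, leukocytes 0.0093 and endothelium and fibroblasts -0.0031. With the deposited values and that array left out, the reversed medians were NF-kB -0.0056, mitosis -0.014, p53 -0.017, apoptosis -0.0047, the unfolded protein response -0.044, Wnt -0.026, splicing -0.0055, leukocytes 0.034 and endothelium and fibroblasts -0.012. With normexp alone, the reversed medians were papillary markers 0.039 and endothelium and fibroblasts -0.086. With quantile normalization alone, the reversed medians were thyroid differentiation 0.016 and papillary markers 0.014. With array weights they were mitosis -0.024, DNA repair -0.0017, apoptosis -0.0012, the unfolded protein response -0.082, ERK output -0.0099, Wnt -0.023, hypoxia -0.024, cholesterol -0.019, oxidative phosphorylation -0.049 and splicing -0.015. With median scaling papillary markers reversed to 0.0021, and with no filter endothelium and fibroblasts to -0.087. The cause of these reversals was not tested beyond leaving out that array.

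Of the named genes, S100A4 and MMP9 kept their direction in every setting run, from -0.69 to -0.28 and from -0.58 to -0.30. Several reversed, namely KLHL15 to -0.0059 with normexp, SLC25A21 to -0.098 with normexp, H2BC14 to -0.0026 with quantile normalization and -0.24 to 0.19 with 1 array left out, H3C1 to -0.048 with array weights and -0.015 to 0.099 with 1 array left out, PSMA6 to -0.024 with array weights and -0.0029 to 0.096 with 1 array left out. MBIP was -0.16 with array weights, -0.018 with normexp, -0.035 with the mean of its probes and -0.19 to 0.43 with 1 array left out, and with empty vector replicate 3 left out -0.17 with quantile normalization, -0.21 with normexp and quantile normalization and -0.24 with the deposited values. FOXA1 was -0.15 with array weights, -0.13 with normexp and -0.074 to 0.35 with 1 array left out, and in the same 3 settings without empty vector replicate 3 it was -0.067, -0.041 and -0.038. PAX9 was -0.87 to 0.23 with 1 array left out, and 0.21, 0.027 and 0.061 in those 3 settings. The cause of these reversals was not tested, and the other values of named genes and of lists outside the histones and ribosomal proteins kept their direction in the settings run (2391 on the same side of the threshold and 11 newly past it). In the similarity of arrays, the mean correlation of empty vector replicate 3 with the other arrays was 0.913 with quantile normalization and 0.924 with normexp. No alternative was run for PTCSC3 itself, which has no probe named here. Signal over background limits the dim genes, whose values rest on few arrays.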

Other observations

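The test of the split counts and of the S100 family splits was set before the splits were computed, and the lists looked at without empty vector replicate 3 were chosen after the results were seen. The arrays show which genes of thyroid identity were measured above background in TPC-1. Of 23 thyroid differentiation genes on the arrays, 8 were well above background on all 8 arrays, among them the transcription factors PAX8 and FOXE1 and thyroglobulin, TG. A further 10 were above background on no array, including the thyrotropin receptor TSHR, the transcription factor NKX2-1, the transporter genes SLC26A4 and SLC5A8, and the deiodinases DIO1 and DIO2. Of 21 papillary carcinoma markers, 16 were above background on all 8 arrays, among them LGALS3, MET, FN1, TIMP1, HMGA2 and RET. Of 35 epithelial and mesenchymal markers, 24 were above background on all 8 arrays, including VIM, CDH2, ZEB1, SNAI2 and the keratins KRT7, KRT8 and KRT18, while the epithelial cadherin CDH1 and the desmosomal gene DSP were above background on none.

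Interferon response genes were above background on all 8 arrays for 45 of 49 genes, with either vector, and only IFNB1 was above background on no array. Of 35 NF-kB and cytokine genes 29 were, including IL6, CXCL8 and CCL2. Of 18 endothelial and fibroblast markers 4 were above background on all 8 arrays (ACTA2, CDH5, ENG and TIE1) and 10 on none, including PECAM1, KDR, DCN and PDGFRA. Of 19 leukocyte markers 11 were above background on all 8 arrays, including CD14, CD68, PTPRC and the lymphocyte genes CD3E, CD8A and CD79A. CD3E had means of -1.29 with the empty vector and -2.40 with PTCSC3, and TG had -2.22 and -2.52. Being above background therefore does not by itself show a cell's identity, for the thyroid genes as for the others. The genes named here were picked out of their lists after their values were seen, and the counts describe detection, not a comparison.

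Whether the arrangement of the arrays by vector is unusual was tested by splitting them in every way into 4 and 4. The number of genes changed was 0 in the real split and at most 0 in the others. A real count of 0 decides nothing, because 35 of 35 splits reach it by construction. For genes at an unadjusted p under 0.05, 6 of 35 splits gave at least the real 505, and the highest of the others gave 1685. For genes with non-overlapping groups, 6 of 35 splits gave at least the real 836, and the highest of the others gave 1951. Chance therefore cannot be excluded for either count. The highest 3 splits gave 1685, 1570 and 1544 genes, several times the real count, which points to a structure of the arrays other than by vector. The split with 1685 genes set empty vector replicates 1 and 2 and PTCSC3 replicates 2 and 3 against the rest, and these are the 4 arrays with the highest 75th percentile of signal (8.43 to 8.88). The split with 1951 non-overlapping genes, and 1570 at an unadjusted p under 0.05, set empty vector replicate 1 and PTCSC3 replicates 2, 3 and 4 against the rest. PTCSC3 replicate 4 (8.19) lay below empty vector replicate 2 (8.43) and PTCSC3 replicate 1 (8.35) on the other side, so the 75th percentile alone does not describe both splits. Relative to the spike-in mean, the 75th percentile was highest on the arrays grouped with empty vector replicate 1 in this split, at -2.91 to -2.83. PTCSC3 replicate 1 came next, close by at -2.98. With empty vector replicate 2 at -3.21, that order does not describe the split with 1685 genes. All 3 of the highest splits grouped empty vector replicate 1 with PTCSC3 replicates 2 and 3. These were the lowest arrays on the first principal component, at -63.7, -39.6 and -38.6. The highest arrays on it, empty vector replicates 3 (157.9) and 4 (34.1), lay on the other side in each split. The remaining arrays lay close together, at -20.6 to -13.7, and were divided differently by each split. These orders were looked at after the splits were seen.

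A hypothesis from the 7 arrays without empty vector replicate 3 is that the calpain and S100 family is lower as a group with PTCSC3. The list median was -0.15 there, with 11 of 13 members lower (camera adjusted p = 0.0326, and adjusted p = 0.655 with an estimated correlation), but the call was lost on these arrays with quantile normalization (0.0671), with normexp and quantile normalization together (0.100) and with the deposited values (0.142). In addition, 3 of 35 splits of these arrays into 3 and 4 gave a median at least as large in size, with 0.19 the highest of the others. Chance therefore cannot be excluded, and the row of the slide follows the vector for this list as well.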
